A study of Homo sapiens with 6 samples.

How the data were processed

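Messenger RNA levels were measured in 6 samples of A172 glioma cells, 1 each for anti-miR-21, mismatch control and miR-21 mimic at 6 h and at 24 h, each paired with mock-treated cells per the labels. Groups were taken from the sample titles. The labels' design text says that no replicates were made, so every value rests on 1 ratio per group, and no p-value, standard deviation across samples or test is given.

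The anti-miR-21 and mismatch samples were hybridised to 2-colour Agilent arrays as fluor-reversed pairs, per the labels, with Cy3 and Cy5 through aminoallyl labelling. The mimic samples were hybridised to Affymetrix arrays with a biotin label, 1 array per sample, and RMA is named in the submitters' processing notes. How the background was corrected, how the dyes were normalized and how pairs were combined are not given in the sources used here. The deposited values are signed ratios, taken as log10 of treated over mock, 1 value per probe and sample. The log base is not stated. Base 10 was taken as likely because with base 2 the middle 50% of Agilent probes would lie within 1.07% to 1.47% of mock, and those of the Affymetrix arrays within 3.33% to 3.80%. That such a spread is too narrow is a judgement, since repeated arrays were not measured here. The direction is not stated either: treated over mock was taken as likely from the title order, mock first, and from the design text, which names mock as the reference, and the dye labels do not say which channel held the mock sample. Both array types were read in the same direction, and an alternative chosen after seeing the data turns 1 of them alone. The deposited column medians on the log10 scale were 0.001 and -0.002 for anti-miR-21 at 6 h and 24 h, 0.0005 and -0.001 for the mismatch control, and 0.001 and 0.006 for the mimic, so the arrays were used as centred by the authors. The values carry no expression level and no detection call, so it is unknown which probes were near background.

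Probes were named through the platform annotation supplied with the values, with symbols updated through gene identifiers and synonyms in a RefSeq gene table of the GRCh38.p14 assembly, used for names and gene lengths only. Of 38851 Agilent probes, 22448 had 1 gene, 83 several and 16320 none; of 43483 Affymetrix probe sets, 25919 had 1 gene and 17564 none. Symbols of 22442 and 25787 of the named probes were matched to the table, and 6 and 132 kept their given symbol. Probes of Y chromosome genes and of X inactivation were left out, 76 and 53. The value of a gene was the median over its probes on the log2 scale, which gave 18057 and 17773 genes, 16178 of them on both array types. Probes of 1 gene differed by a median SD of 0.05 to 0.06 (log2) on the Agilent arrays, over 3603 genes with 2 or more probes, and of 0.15 and 0.18 on the Affymetrix arrays, over 5884 genes. The spread of the ratios differed too: the interquartile range was 0.10 to 0.14 on the Agilent arrays and 0.31 and 0.36 on the Affymetrix arrays. Read as base 2, the Affymetrix values would have interquartile ranges of 0.09 and 0.11, near those of the Agilent arrays. A log base that differs between the array types was therefore not excluded, and with base 2 no mimic gene passed 1.5-fold. A count past a fixed fold is therefore not comparable between the array types.

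Counts are of genes at least 1.5-fold higher or lower (log2 0.58). The difference of anti-miR-21 and mismatch control is the difference of their log2 ratios. For each of 25 gene lists, the median was set against 10000 seeded random lists of the same size drawn from all genes of that array type, and a list was said to lie outside the range of random lists at or beyond the 0.1 or 99.9 percentile. Random lists could not be matched on expression, and they were not matched on gene length. An alternative matched them on the mean absolute ratio of each gene over the arrays of its type. Of 200 list results, 31 lay outside and 22 of these did with matched lists. Overlaps are given beside the number that independent lists would share. If 2 treatments shared a mock sample, their ratios would correlate without any effect, at r = 0.50 in a simulation of unchanged samples of equal spread. The labels do not say whether they did, and the observed r of anti-miR-21 and mismatch control was 0.125 at 6 h and 0.0379 at 24 h. The simulation held no noise of separate hybridisations, which would lower r, so these values do not show whether a mock was shared.

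The gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, for the difference of anti-miR-21 and mismatch control and for the mimic, the 10 highest and 10 lowest genes by the weaker of the 2 times in 1 direction. For anti-miR-21 and the mismatch control against mock it takes 5 and 5, and for each single time of each treatment 3 and 3. It also allows any member of the lists of reported targets and of metalloproteinase regulators, and from each other list up to 4 members with the largest mean over the 2 times. A planned comparison of genes with a miR-21 seed site in the 3' UTR was not run, since no transcript sequences were used here.

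Alternatives were thresholds of 2 and 1.3, centring each array on its median, scaling the arrays of 1 type to the same median absolute deviation, the probe with the largest absolute mean per gene, every probe counted alone, log base 2, the ratio with its sign turned, list means, matched random lists, lists without members under 0.1 at both times, and the targets without the metalloproteinase regulators. The procedure was tested on simulated data made by shuffling the 24 h values over genes, with 200 genes changed by known folds. Of genes changed 2-fold, 99% were counted for anti-miR-21 and for the mismatch control at 24 h and 90.5% for the mimic at 24 h, and of genes changed 1.5-fold 49%, 54% and 45%. The shares at 1.5-fold follow from the setting, since the planted change equals the threshold. Lists of 60 genes shifted by 0.2 (log2) were found in 100%, 100% and 95.5% of draws, and those shifted by 0.1 in 100%, 100% and 28.5%. Lists with no shift were called in 0%, 1.5% and 0.5%. Shuffled values hold no link between genes, so these rates do not bear on lists whose genes move together. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.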

Results

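The data covered mRNA levels in A172 cells, an established human glioma line, after treatment with an antisense oligonucleotide against the microRNA miR-21, a mismatch control oligonucleotide, or a duplex that mimics miR-21. Each treatment was compared with mock-treated A172 cells at 6 h and at 24 h, which gave 6 groups of 1 ratio each. The antisense and mismatch samples were measured on 2-colour Agilent arrays as fluor-reversed pairs, and the mimic samples on Affymetrix arrays. The design had no replicates, so no test was made and no error is given. A gene was called higher or lower at a ratio of at least 1.5-fold, a rule of size, and the small number of arrays limits the precision of every value. Ratios are printed as log2 of treated over mock. That direction is likely, from the order of the sample titles and from mock being named as the reference, but it is not stated, and the log base of the deposited values was taken as 10, also as likely. The 6 h and 24 h ratios came from separate samples, and 18057 genes were measured on the Agilent arrays and 17773 on the Affymetrix arrays.

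The first comparison asked which transcripts differ once miR-21 is inhibited. With anti-miR-21 at 24 h, several transcripts reported as miR-21 targets were higher than in mock cells, among them RECK, a membrane-anchored inhibitor of matrix metalloproteinases, at 1.82-fold, and PDCD4, an inhibitor of translation initiation, at 1.67-fold. The lowest transcripts at that time were ESM1, an endothelial-cell-specific proteoglycan (log2 -1.57), HBEGF, a ligand of the EGF receptor (-1.23), and PTX3, a soluble pattern-recognition protein (-1.16). At 6 h the lowest transcript was EGR1, an immediate early transcription factor, at log2 -2.72, or 6.59-fold lower. Each transcript named so far was measured by a single probe. In all, 8 genes were higher and 8 lower at 6 h, and 41 higher and 56 lower at 24 h. With the arrays scaled to the same median absolute deviation these counts were 12 and 15 at 6 h and 14 and 32 at 24 h.

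The genes past the threshold at both times with anti-miR-21 were KLHL15, MKNK2 and WEE1 on the higher side and ATF3, CLEC17A, MALAT1, SETDB2 and SSR3 on the lower side. KLHL15, an adaptor of a CUL3 ubiquitin ligase, was 1.90-fold higher at 6 h and 2.46-fold higher at 24 h, against log2 0.05 and 0.08 with the mismatch control. WEE1, the kinase that holds CDK1 inactive, stood at log2 0.62 and 0.69, and MKNK2, a kinase of the translation factor eIF4E, at 0.64 and 0.65. TNFRSF11B, the decoy receptor osteoprotegerin, was at 0.66 and 0.58, and TET1, a 5-methylcytosine dioxygenase, at 0.52 and 0.56. SETDB2, a histone methyltransferase, was at -0.86 and -0.93, and ATF3, a stress-induced transcription factor, at -0.77 and -0.72. MALAT1, a long nuclear RNA, was lower with both oligonucleotides, at -2.29 and -0.64 with anti-miR-21 and at -1.31 and -1.12 with the mismatch control. CLEC17A and SSR3 were lower with both oligonucleotides as well, CLEC17A at -1.38 with anti-miR-21 and -1.26 with the mismatch control at 6 h. LHCGR, the luteinizing hormone receptor, was among the highest at 6 h (0.94) but not at 24 h (-0.11). ANGPTL7, a secreted angiopoietin-like protein (1.54), and HNMT, which methylates histamine (0.97), were among the highest at 24 h. Of the genes named in this paragraph, only KLHL15, ATF3, TNFRSF11B and HNMT were measured by more than a single probe.

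Of the 59 measured genes on the list of reported miR-21 targets, 40 lay above 0 with anti-miR-21 at 24 h and 7 were at least 1.5-fold higher: RECK (log2 0.86), PDCD4 (0.74), FAM3C (0.72), RASGRP1 (0.70), GLCCI1 (0.67), CPEB3 (0.67) and APAF1 (0.65), the last of these the scaffold of the apoptosome. Another 2 members were lower, PLAT, which encodes tissue plasminogen activator (-1.08), and TNFAIP3, an inhibitor of NF-kB signalling (-0.75). RECK, PDCD4, RASGRP1, GLCCI1, CPEB3 and PLAT were each measured by a single probe, unlike FAM3C, APAF1 and TNFAIP3. The list's median was 0.10, at percentile 100 of 10000 random lists of the same size. With the mismatch control at 24 h its median was 0.03 (percentile 99.5), and no member passed 1.5-fold. At 6 h with anti-miR-21 the median was 0.04 and no member passed. This list was written from general knowledge and holds genes such as RECK and TIMP3 that the study may have picked on these samples, so its direction is not independent evidence.

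**Figure D1:**
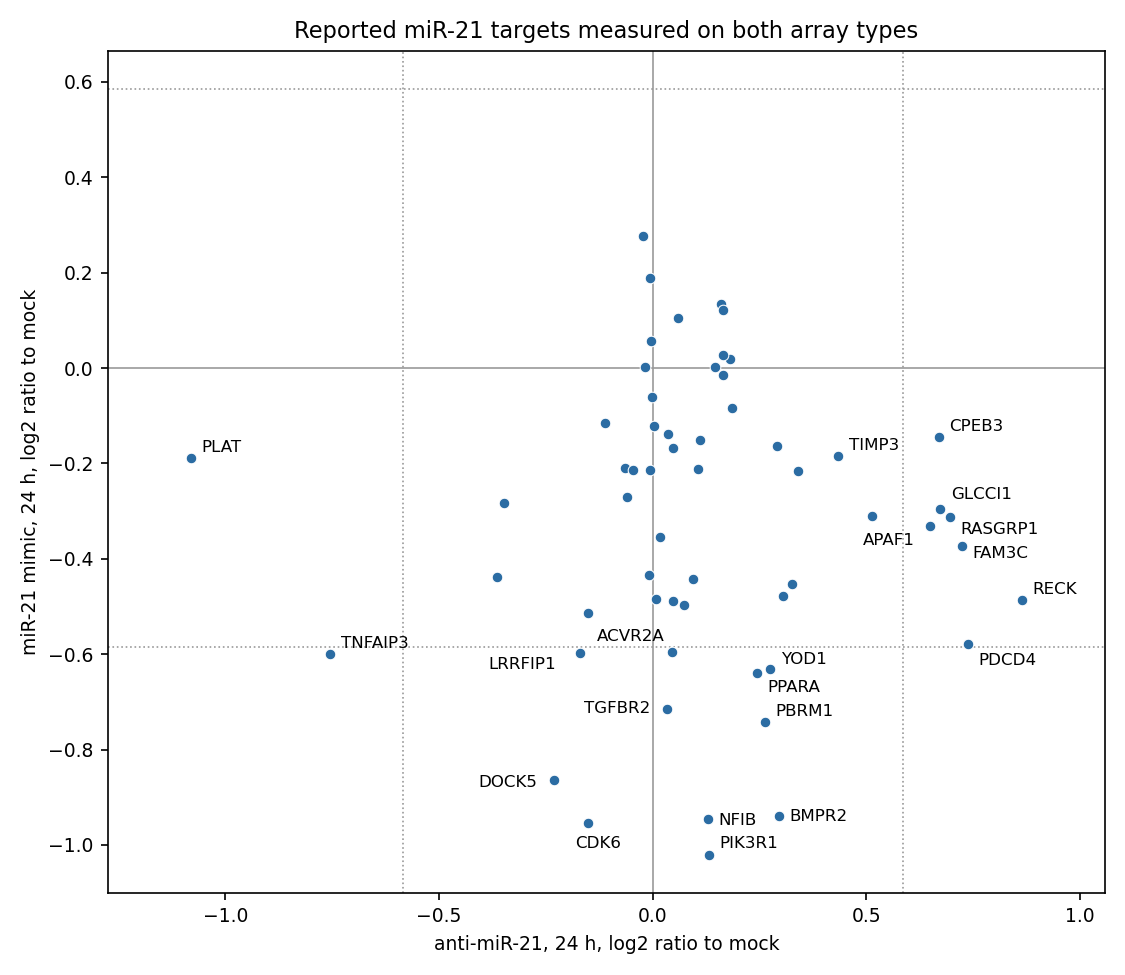
Log2 ratio to mock at 24 h of the 58 reported miR-21 targets measured on both array types, with anti-miR-21 on the horizontal axis and the miR-21 mimic on the vertical axis; each point is 1 gene and dotted lines mark 1.5-fold. At the lower right, higher with anti-miR-21 and lower with the mimic, lie 33 genes, RECK and PDCD4 among them.

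The title of the series names regulators of matrix metalloproteinases. Of 18 measured inhibitors and regulators, 1 was higher with anti-miR-21 at 24 h, RECK, and 2 were lower, PLAT and the urokinase receptor PLAUR (-0.67); the list's median was -0.04 (percentile 10.5). TIMP3, a matrix-bound inhibitor of metalloproteinases, had a median of 0.43 over 2 probes that differed, at 0.85 and 0.02. TIMP1 was at -0.09, TIMP2 at 0.02 and TIMP4 at 0.07. Among 22 metalloproteinases, the stromelysin MMP10 was at -0.76, the collagenase MMP1 at -0.47 and MMP3 at -0.31, while the same transcripts were at 0.61, 0.44 and 0.33 with the mismatch control. The metalloproteinase list had a median of -0.07 with anti-miR-21 at 24 h, with 18 of 22 members below 0 and 1 past the threshold (percentile 0.44, short of the limit of 0.1 used for lists). ADAMTS9, an aggrecanase, was at -0.78.

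Immediate early genes were lower as a group with anti-miR-21. At 6 h, 20 of 22 measured members lay below 0 and 2 passed 1.5-fold, EGR1 and ATF3, with a median of -0.24. At 24 h, 17 lay below 0 and 5 passed, among them the MAP kinase phosphatases DUSP1 (-1.002) and DUSP6 (-0.95), with a median of -0.20 (percentile 0 at both times). EGR1 was also at -0.72 with the mismatch control at 6 h. NF-kB targets and inflammatory cytokines were lower at 24 h, with 26 of 28 below 0, 2 past the threshold and a median of -0.14 (percentile 0). Members of that list included IL11 (-0.63), a cytokine of the interleukin-6 family, LIF (-0.49) and TNFAIP3. The list of the integrated stress and unfolded protein response had medians of -0.09 at 6 h and -0.12 at 24 h (percentile 0 at both), with ATF3 past the threshold both times and the endoplasmic reticulum chaperone HSPA5 at -0.24 and -0.36. The 6 h result was at percentile 0.14 among random lists matched on the size of the genes' ratios, short of the limit of 0.1, so it lay within their range.

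Cell cycle transcripts of the G2 and M phases were slightly higher with anti-miR-21 at 24 h. Of 26 members, 25 lay above 0, none passed 1.5-fold and the median was 0.21 (percentile 100). Examples were KIF20A, a mitotic kinesin (0.45), CDK1, the mitotic kinase (0.37), and cyclin A2, CCNA2 (0.25). S phase genes showed no such shift, with a median of 0.00. Extracellular matrix and adhesion genes had a median of -0.10 (21 of 32 below 0, percentile 0), with LOX, the collagen cross-linking oxidase, at -0.61, the integrin subunit ITGA2 at -0.42 and the collagen COL3A1 at 0.51. The mismatch control gave a like median of -0.09, and the difference of both was -0.02 (percentile 31.0). The connective tissue growth factor CCN2, a TGF-beta target, was at -0.76 at 24 h, while the TGF-beta list as a whole had a median of 0.03 (percentile 90.9).

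The mismatch control was meant as the background for anti-miR-21, and it carried a profile of its own that was at least as large. Here 11 genes were higher and 25 lower at 6 h, and 55 higher and 117 lower at 24 h. Of the 25 genes lower at 6 h, 21 were also lower at 24 h, where independent lists would share 0.162. S phase transcripts were lower as a group at 24 h, and p53 targets and histone transcripts were higher.

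The highest transcript with the mismatch control was NDUFC2, a subunit of mitochondrial complex I, at log2 1.27 at 6 h and 2.14 at 24 h, with both of its probes past 1.5-fold at each time. SNORA72, a small nucleolar RNA (0.81 and 1.02), ANXA11, a calcium-binding annexin (0.67 and 1.0004), TRIM69, a ubiquitin ligase (0.75 and 0.69), and the neurotrophic factor CNTF (0.51 and 0.56) followed. SLC5A7, the choline transporter, was at 1.18 at 6 h and 0.08 at 24 h. KHDRBS2 was at 1.12 and the uncharacterised MGC2889 at 1.14 at 24 h. On the lower side, NET1, a RhoA exchange factor, was at -1.15 and -1.25, LIPT1, a lipoyltransferase, at -1.15 and -1.12, TMCC1, an endoplasmic reticulum membrane protein, at -1.25 and -1.09, and PHIP, a bromodomain protein, at -1.06 and -1.69. The lowest at 24 h were DYNLT2B, a dynein light chain (-3.09), USP16, a histone H2A deubiquitinase (-2.11), and TOP2B, a DNA topoisomerase (-1.91). Each of these 7 lower genes was measured by a single probe.

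S phase genes were lower with the mismatch control at 24 h. Of 23 members, 22 lay below 0, and the median was -0.25 (percentile 0). RRM2, a subunit of ribonucleotide reductase, was at -0.76 and the replication factor GINS2 at -0.54. Of 26 G2 and M phase genes, 2 were lower past the threshold at 24 h, the spindle motor KIF11 (-0.94 at 6 h and -1.59 at 24 h) and the checkpoint kinase TTK (-0.59 and -0.66), while the list's median was -0.04 (percentile 6.36). The p53 targets were higher at both times, with 19 of 23 above 0 at 6 h (median 0.13) and 21 of 23 at 24 h (median 0.28), percentile 100 each time. TP53INP1, a pro-apoptotic p53 target, was at 0.60 at 24 h, the cell cycle inhibitor CDKN1A at 0.55, the death receptor FAS at 0.51 and MDM2, the ligase that degrades p53, at 0.35. Of the 23, 1 passed 1.5-fold.

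Replication-dependent histone transcripts had the largest list median of the Agilent arrays with the mismatch control, 0.44 at 24 h, with 13 of 14 above 0 and 3 past 1.5-fold: H2AC6 (0.81), H2BC21 (0.76) and H4C14 (0.62). At 6 h the median was 0.04. Oxidative and metal stress genes had a median of 0.26 at 24 h, with 12 of 17 above 0. The cystine transporter SLC7A11 (0.68), the aldo-keto reductases AKR1C1 (0.56) and AKR1C3 (0.44) and the haem oxygenase HMOX1 (0.26) were among them. The integrated stress list had a median of 0.08 at 24 h (percentile 99.94) and the TGF-beta list 0.10 (percentile 99.93), with TGFBI at 0.51 and TGFBR1 at 0.44. Extracellular matrix genes had a median of -0.09 (percentile 0.010), with 21 of 32 below 0. Against random lists matched on ratio size these last 3 results were at percentiles 98.2, 99.5 and 0.44, within their range. The metalloproteinase regulators had a median of -0.07 (percentile 1.265), with the urokinase protease PLAU at -0.75. Interferon-stimulated genes had a median of 0.03, while TRIM22 (-0.86) and DDX60 (-0.74) were lower.

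The difference of anti-miR-21 and mismatch control set the antisense sequence against its control, and either of the 2 can give rise to a difference. It would cancel the mock sample only if both shared one, which the labels do not say. At 6 h, 35 genes were at least 1.5-fold higher with anti-miR-21 than with the mismatch control and 23 lower, at 24 h 213 and 157, and at both times 24 and 11. Most of the genes furthest apart at both times were close to mock with anti-miR-21 and away from mock with the mismatch control, as LIPT1, NET1, PHIP, TMCC1, KIF11, the antisense RNA LPP-AS2, RAB3GAP2 and the helicase BLM on one side and NDUFC2, SNORA72, ANXA11, TRIM69, MAP3K13 and the phosphate transporter SLC20A2 on the other. LPP-AS2 differed by 0.86 at 6 h and 1.81 at 24 h, BLM by 0.77 and 1.09, RAB3GAP2 by 0.82 and 1.15, MAP3K13 by -0.66 and -1.04, and SLC20A2 by -0.61 and -1.05. Of the 3 probes of RAB3GAP2, 1 read -0.14 and 0.34 with the mismatch control, so this gene's difference rests on the others. The exceptions were KLHL15 (difference 0.88 and 1.22) and MKNK2 (0.79 and 0.83), which were higher with anti-miR-21, and SETDB2 (-1.003 and -0.96), SLC35G1 (-0.66 and -0.79) and ATF3 (-0.62 and -1.36), which were lower with it. ATF3 owed part of its 24 h difference to the mismatch control, where it was at 0.64, against -0.72 with anti-miR-21. SLC5A7 differed by -0.83 and -0.66, at 6 h mainly through the mismatch control and at 24 h mainly through anti-miR-21, where it was at -0.58.

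**Figure D2:**
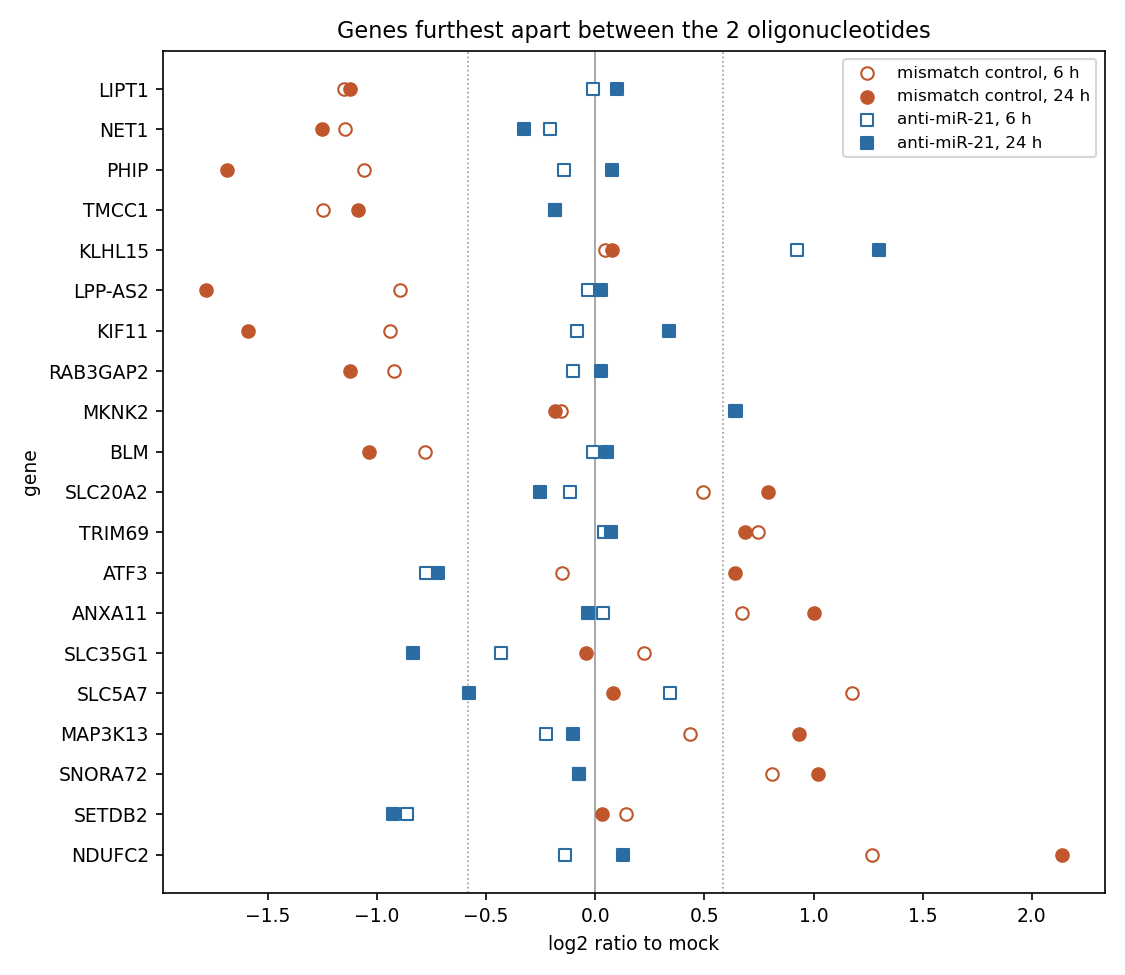
Log2 ratio to mock of the 10 genes most higher and the 10 most lower with anti-miR-21 than with the mismatch control at both times, with 1 point per treatment and time (circles, mismatch control; squares, anti-miR-21; open, 6 h; filled, 24 h) and dotted lines at 1.5-fold. NDUFC2 reaches 2.14 with the mismatch control and 0.13 with anti-miR-21 at 24 h, whereas KLHL15 is 2.46-fold higher with anti-miR-21 and at 0.08 with the mismatch control.

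Among the reported targets, 4 of 59 were higher in this difference at 24 h, CPEB3 (1.25), APAF1 (0.78), RECK (0.76) and FAM3C, and the same 2, PLAT (-0.80) and TNFAIP3 (-1.03), were lower. CPEB3, a regulator of mRNA polyadenylation, owed part of its value to the mismatch control, where it was at -0.58. The list's median was 0.10 (percentile 100), but at percentile 99.8 among lists matched on ratio size, within their range. The G2 and M phase list had a median difference of 0.25, with 25 of 26 above 0 and 4 past 1.5-fold (KIF11 1.93, TTK 0.89, HMMR 0.84 and CENPE 0.59). Its median was 0.21 with anti-miR-21 against -0.04 with the mismatch control, but no member passed 1.5-fold with anti-miR-21. KIF11 owed its difference mainly to the mismatch control, at -1.59 against 0.34 with anti-miR-21. TTK was also at least 1.5-fold lower with the mismatch control. The S phase list was at 0.27, with 20 of 23 above 0 and RRM2 at 0.80 (percentile 100 for both lists). Lower groups at 24 h were the histones (median -0.38, 12 of 14 below 0), oxidative and metal stress genes (-0.25, 15 of 17, with HMOX1 at -0.65) and the integrated stress list (-0.19, 21 of 25, with SESN2 at -0.70), each at percentile 0. The histones and oxidative stress genes owed this mainly to the mismatch control: their medians were 0.09 and -0.03 with anti-miR-21, against 0.44 and 0.26. The same held for the S phase list (0.00 against -0.25) and, at 24 h, for the p53 targets (0.02 against 0.28). The p53 targets were at -0.18 at 6 h and -0.22 at 24 h, with FAS at -0.62 and GADD45A, a growth arrest gene, at -0.77. Immediate early genes were at -0.21 and -0.16, with EGR1 at -2.0045 at 6 h, and NF-kB targets at -0.14 at 24 h, with IL11 at -0.84 and IL1A at -0.78. The integrated stress list at 6 h was at -0.09. Against matched lists, 4 of these results lay within the random range: p53 targets (percentile 0.37), immediate early genes (0.36) and NF-kB targets (0.14) at 24 h, and the integrated stress list at 6 h (0.44).

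The last treatment asked which transcripts are lower when miR-21 is added. The samples held no control duplex, and the mimic was set against mock only. An effect of the miR-21 sequence therefore cannot be told apart from one of delivering any duplex, here and in the mimic results below. With the mimic, lower genes outnumbered higher ones at 24 h, 520 against 143 of 17773, while at 6 h the counts were close, 106 against 111. With the probe set of the largest absolute mean per gene they were 1058 against 231 at 24 h and 295 against 190 at 6 h. Reported miR-21 targets were lower as a group at 24 h, with 12 of 61 at least 1.5-fold lower and none higher. Only 2 genes were higher at both times, MS4A2 and PAOX, against 21 lower, where independent lists would share 0.893 and 3.10.

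The 12 lower targets were PIK3R1, the regulatory subunit of PI3 kinase (-1.02), the cell cycle kinase CDK6 (-0.95), the transcription factor NFIB (-0.94), the BMP receptor BMPR2 (-0.94), DOCK5 (-0.86), the chromatin remodelling subunit PBRM1 (-0.74), the TGF-beta receptor TGFBR2 (-0.72), PPARA (-0.64), YOD1 (-0.63), TNFAIP3 (-0.60), LRRFIP1 (-0.60) and ACVR2A (-0.59). Probe sets differed widely for ACVR2A (-0.08 and -1.11) and for CDK6, where 4 probe sets ranged from -1.61 to 0.10. They also differed for LRRFIP1 (-0.98 to -0.12), PPARA (-0.79 to -0.06), BMPR2 (-0.97 to -0.20) and PBRM1 (-0.99 to -0.41). PDCD4 lay just short of the threshold at -0.58, RECK was at -0.49, APAF1 at -0.33 and TIMP3 at -0.19. Of the 61 measured members, 50 lay below 0 and the median was -0.27 (percentile 0). Longer genes had lower ratios with the mimic at 24 h (rank correlation -0.29 over genes on both array types). Random lists were not matched on gene length, so a part of this shift from length was not excluded. At 6 h the median was -0.11 with 49 below 0 (percentile 0.17) and none past 1.5-fold. The housekeeping list was also at -0.11 at 6 h with the mimic. The caution on how this list was made holds here as well. Of the metalloproteinase regulators, PLAU was at -0.59 at 24 h and the protease inhibitor A2M at 0.68, and the list's median was -0.08 (percentile 7.33). The metalloproteinase list had a median of 0.00, with 1 of 22 members past 1.5-fold, MMP8 (0.64), which was named after its value was seen. MMP17 (0.54) and MMP7 (-0.54) lay short of it.

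Beyond the lists, the transcripts lower at both times with the mimic included LRRC37A3 (-0.95 and -0.89), NEK7, a mitotic kinase that also serves the NLRP3 inflammasome (-0.87 and -1.41), GOLGA8B (-1.09 and -0.80) and ATF2, a stress-responsive transcription factor (-0.76 and -0.76). PLGLB1 (-0.77 and -0.74), TPTE (-0.73 and -0.77), the mitochondrial ribosomal protein MRPL42 (-0.69 and -0.71), tissue factor, F3 (-0.68 and -0.76), the DNA damage kinase ATR (-0.68 and -0.70) and RUNX1-IT1 (-0.68 and -1.002) belonged there too. On the higher side, MS4A2, a chain of the IgE receptor, was at 0.91 and 1.06, PAOX, a polyamine oxidase, at 0.61 and 0.82, TMEM252 at 0.49 and 1.17 and TERC, the telomerase RNA, at 0.59 and 0.51. CST11, CORT, TEKTL1, FAM225A, CPLANE2 and INSRR were the others of the 10 highest by the weaker time. Each of these 10 was measured by a single probe set, as were the lower genes named above except NEK7 and GOLGA8B. Ranked at 24 h, the lowest were SHTN1 (-1.66), AADAC (-1.53) and TMEM245 (-1.51), and the highest RPSAP15, a ribosomal protein pseudogene (1.60). Ranked at 6 h, RSPO1 (0.92) and KRTAP12-1 (0.91) stood among the highest, and LRRCC1 (-1.15) and NUDT4B (-1.12) were the lowest. HINT3 was at 1.08 at 6 h and -1.46 at 24 h, a gene whose 2 probe sets differed widely.

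Several other groups held lower members with the mimic. In the microRNA and RNAi machinery, 3 of 14 genes were at least 1.5-fold lower at 24 h: TNRC6B, a scaffold of the silencing complex (-1.27), AGO4, an Argonaute protein (-1.09), and DICER1, which processes precursor microRNAs (-0.74). The median of that list was -0.13 (percentile 2.87). Extracellular matrix genes had a median of -0.16 at 6 h (25 of 33 below 0, percentile 0.030), and at 24 h VCAN and ITGAV (-0.78 each) and FBN1 (-0.67) passed the threshold, with a median of -0.09 (percentile 1.73). Apoptosis genes had a median of -0.17 at 6 h (16 of 23 below 0, percentile 0.090), with the caspase inhibitor XIAP at -0.36 and at -0.73 at 24 h. Housekeeping genes had a median of -0.11 at 6 h with the mimic (percentile 8.28). Random lists were not matched on expression, so how far the 6 h medians are particular to the matrix and apoptosis lists is open. The proliferation marker MKI67 (-0.997), CENPF (-0.73) and KIF11 (-0.60) were lower at 24 h, while the G2 and M phase list had a median of 0.03. GCLM, a subunit of glutamate-cysteine ligase (-1.06), and SLC7A11 (-0.79) were lower in the oxidative stress list (median -0.08). In the TGF-beta list TGFBR2 and BMPR2 passed (median -0.10), and ADAMTS1 (-0.62) did so among the ADAM and ADAMTS proteases (median -0.16, percentile 0.67). The p53 targets had a median of -0.06, with TP53INP1 at -0.70 and MDM2 at -0.54. The caution on gene length given for the reported targets holds for the 24 h values here too. A part of these lower ratios from length was not excluded.

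Anti-miR-21 and the mimic were then set against each other over the 16178 genes on both array types, since opposite treatments would place genes on opposite sides. At 24 h, 3 genes were higher with anti-miR-21 and lower with the mimic, ANGPTL7, SKIDA1 and WEE1, where independent lists would share 1.11, and none went the other way. In the same direction, 7 were lower with both (1.47 for independent lists), DUSP6, TNFAIP3 and ESM1 among them, and 1, INSL5, was higher with both. SKIDA1 and INSL5 fall outside the rule for named genes and were chosen after their values were seen, as were 5 of the 7 genes named next. With the difference from the mismatch control in place of anti-miR-21, 15 genes were higher there and lower with the mimic, against 5.65 for independent lists, but 12 were lower there and lower with the mimic, against 4.43. Genes lower with both the mismatch control and the mimic numbered 11, against 3.11, and 7 of the 15 are among these: ASAP2, ATR, CPA4, KIF11, LNPK, PRKDC and PSD3. Across genes, which are not independent replicates, Pearson's r at 24 h was -0.05 and Spearman's rho -0.07, and at 6 h they were 0.19 and 0.23. These are among 28 correlations across genes that were computed. Of the 58 reported targets on both array types, 33 were higher with anti-miR-21 and lower with the mimic at 24 h, where 32.3 would be if the directions were independent (39 higher with anti-miR-21 and 48 lower with the mimic). The others were 15 lower with both, 6 higher with both and 4 the reverse. All of these comparisons assume that both array types run in the same direction.

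The remaining lists stayed within the range of random lists in each treatment at each time. At 24 h the medians with anti-miR-21, mismatch control and mimic were -0.01, -0.03 and -0.02 for the heat shock response, 0.06, 0.00 and 0.17 for cholesterol biosynthesis, and 0.06, 0.03 and 0.07 for hypoxia and glycolysis. STARD4, a sterol carrier, was at -0.46 and INSIG1 at -0.52 with the mimic, and ANKRD37, a hypoxia-induced gene, was at 0.68 with anti-miR-21. The glial and glioma identity list had medians of -0.05, 0.00 and -0.07, with the stem cell factor SOX2 at 0.47 with anti-miR-21 and -0.36 with the mismatch control. Markers of other cell types were near 0: neuronal genes at 0.00, -0.01 and -0.03, epithelial genes at 0.00, -0.04 and 0.04, and blood and endothelial genes at 0.01, -0.01 and -0.06. Housekeeping genes were at -0.05, -0.05 and -0.04.

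**Figure D3:**
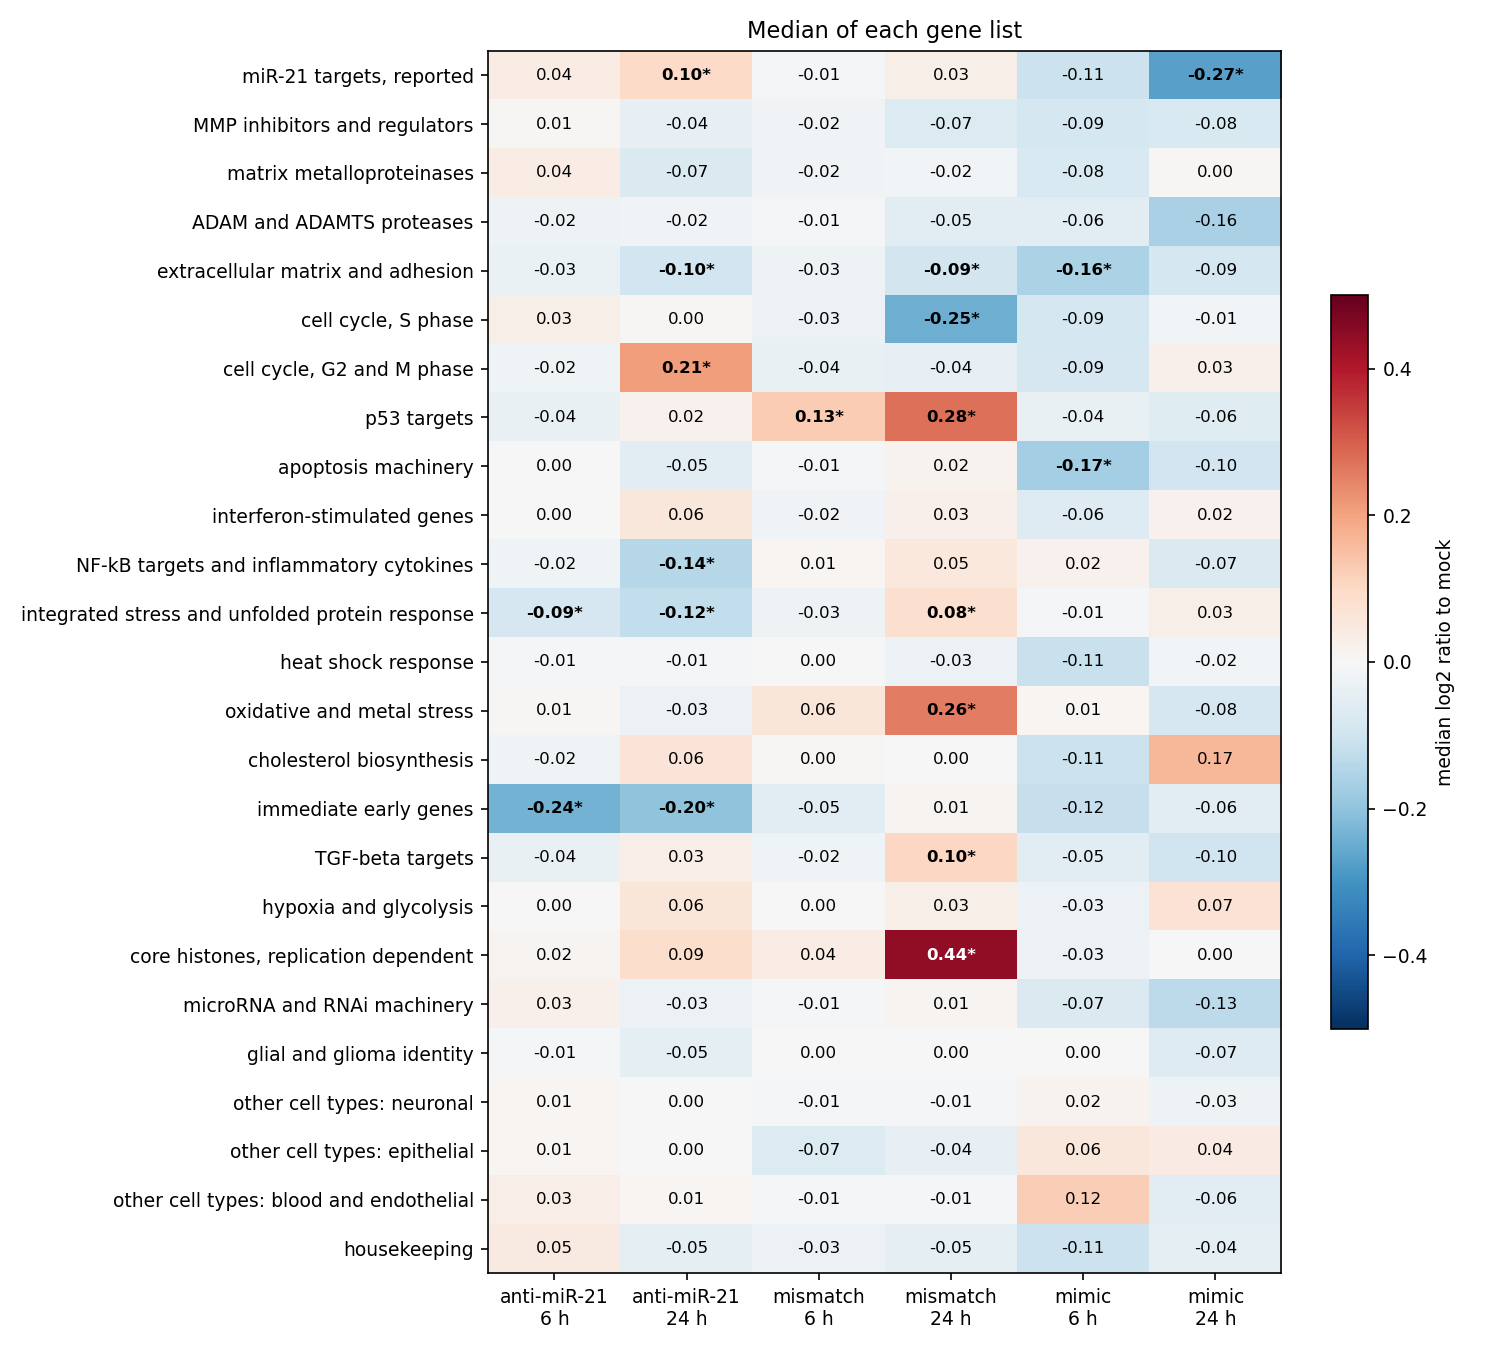
Median log2 ratio to mock of each of the 25 gene lists in the 6 groups, with colour from blue (lower) to red (higher); an asterisk marks medians within the outermost 0.1% on either side of 10000 random lists of the same size. The histone list stands at 0.44 with the mismatch control and the reported miR-21 targets at -0.27 with the mimic, both at 24 h.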

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

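Of the tests named here, all but the probe comparison of the mismatch genes were chosen only after the result was seen.

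With the mimic, 3 genes lay past 1.5-fold in opposite directions at the 2 times. Higher at 6 h and lower at 24 h was 1 gene, where independent lists would share 3.25. The reverse held for 2 genes, where they would share 0.853, so the number of such genes does not stand out. HINT3 differed between 24 h and 6 h by -2.54 (log2), SDHAF3 by 1.299 and ZNF92 by 1.28, and these differences were not tested, since each time has 1 sample. SDHAF3 was at -0.60 and then 0.70, and ZNF92 at -0.67 and then 0.61. For HINT3 1 probe set read 2.24 and -2.51 and the other -0.07 and -0.41, so the difference rests on 1 probe set. SDHAF3 and ZNF92 fall outside the rule for named genes and were chosen after their values were seen.

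Probe sets without a gene name, which the comparisons leave out, also held ratios past 1.5-fold with the mimic: 420 of 17564 at 6 h and 853 at 24 h. At 24 h 588 of these were lower and 265 higher. The counts were 2.39% and 4.86% of the unnamed probe sets. Of all 43483 Affymetrix probe sets, 1008 passed at 6 h and 2562 at 24 h. The unnamed share was thus close to that of the whole array at 6 h and lower at 24 h. On the Agilent arrays, unnamed probes past 1.5-fold at 24 h numbered 53 of 16320 for anti-miR-21 and 161 for the mismatch control.

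The genes lower with the mismatch control were weighed because that oligonucleotide serves as the control. Noise of single array pairs was argued against: the 25 genes lower at 6 h had a median of -1.04 at 24 h, 24 of them below 0, while the lowest median of 10000 random gene sets was -0.10. A response to any antisense oligonucleotide was argued against as the cause of the whole set, since the 117 genes lower at 24 h had a median of -0.82 with the mismatch control and 0.0159 with anti-miR-21 (SD over genes 0.21). A hybridisation artefact at single probes stays open and cannot be told apart from a lower transcript: over 11 genes with several probes and 1 at least 2-fold lower, the other 17 probes had a median of -0.0767, just beyond the lowest median of random probe sets (-0.0688) but short of the bound of -0.3 set beforehand, with 7 of them at least 1.5-fold lower. A sequence-specific effect of the mismatch oligonucleotide on other transcripts may remain, but its sequence was not used here and this was not tested.

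Immediate early genes lower with anti-miR-21 could reflect a mock culture with raised early-gene levels. A mock shared with the mismatch control was argued against at 6 h, where the median difference of the 2 treatments was -0.21, at percentile 0 of random lists. A mock culture of its own for anti-miR-21 cannot be told apart from an effect of the oligonucleotide: the mismatch control's median at 6 h was -0.0522, which bears on it only if the mock was shared, and the ratios do not give each mock's level. An effect of inhibiting miR-21 stays open and was not tested further.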

How the results depend on the processing

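All settings here were planned except the turning of 1 array type alone, which was chosen after seeing the data, and the cause of a difference was not tested unless the way the setting is built shows it. The numbers of genes past the threshold at 6 h, at 24 h and at both times were 16, 97 and 8 for anti-miR-21, 36, 55 higher plus 117 lower, and 25 for the mismatch control, 217, 663 and 23 for the mimic, and 58, 370 and 35 for the difference of anti-miR-21 and mismatch control. By construction, a threshold of 2-fold gave fewer: 3, 9 and 1, 9, 43 and 6, 5, 69 and 0, and 8, 75 and 2 in the same order. A threshold of 1.3-fold gave 77, 385 and 36, 127, 565 and 81, 1550, 2565 and 239, and 213, 1179 and 106. Every probe on its own, unnamed probes included, gave 49, 200 and 17, 107, 421 and 67, 1008, 2562 and 120, and 151, 774 and 84. With log base 2 almost none were left: 2, 0 and 0, 0, 3 and 0, 0, 0 and 0, and 1, 5 and 0. The probe with the largest absolute mean gave 28 genes for anti-miR-21 at 6 h and 485, 1289 and 67 for the mimic. Arrays scaled to the same median absolute deviation gave 27 and 46 for anti-miR-21 at 6 h and 24 h and 60 for the mismatch control at 6 h. With that scaling the anti-miR-21 split at 24 h was 14 higher and 32 lower, against 41 and 56 (30.4% and 42.3% higher), and at both times 1 and 5, against 3 and 5 (16.7% and 37.5%). The mimic's split at 6 h was 190 higher and 295 lower with the probe of the largest absolute mean, against 111 and 106 (39.2% and 51.2% higher). The share higher was also nearer to even for the mismatch control at 24 h with a threshold of 1.3-fold (48.0%) and with every probe (46.6%), against 32.0%, and for the mimic at 24 h with 1.3-fold (40.7%), against 21.6%. It was further from even at 2-fold: 5 higher and 38 lower for the mismatch control (11.6%) and 2 and 7 for anti-miR-21 (22.2%, against 42.3%) at 24 h. At 6 h the 2-fold split was 0 higher and 3 lower for anti-miR-21, against 8 and 8. For the mimic at 6 h it was 1 and 4, against 111 and 106. With every probe, the mismatch control at both times had 22 higher and 45 lower (32.8%), against 4 and 21 (16%). Centring each array on its median moved none of the 36 counts or 200 list medians beyond the limit set for a difference.

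The median of the reported targets was 0.0360 and 0.0953 with anti-miR-21 at 6 h and 24 h, -0.0093 and 0.0296 with the mismatch control, 0.0241 and 0.10 in the difference, and -0.1080 and -0.2697 with the mimic. With the probe of the largest absolute mean it was 0.0664 and 0.1272 with anti-miR-21, 0.0538 in the difference at 6 h, and -0.1492 and -0.4186 with the mimic. The mean over the list was 0.1214 with anti-miR-21 and 0.0091 with the mismatch control at 24 h, and 0.0581 in the difference at 6 h. Without members under 0.1 at both times it was 0.0566 and 0.1648 with anti-miR-21, -0.0213 and 0.0485 with the mismatch control, and 0.0538 and 0.1996 in the difference. In the difference at 24 h its percentile was 99.79 with matched random lists, against 100.

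If the ratios are mock over treated, every direction turns, by construction. The target medians would be -0.0360 and -0.0953, 0.0093 and -0.0296, -0.0241 and -0.10, and 0.1080 and 0.2697. Other lists would turn as follows, with the main value of the opposite sign: extracellular matrix 0.0950 (anti-miR-21, 24 h), 0.0928 (mismatch control, 24 h) and 0.1578 (mimic, 6 h); S phase 0.2455 (mismatch control, 24 h) and -0.2741 (difference, 24 h). G2 and M phase would be -0.2094 with anti-miR-21 and -0.2536 in the difference at 24 h. The p53 targets would be -0.1269 and -0.2764 with the mismatch control and 0.1820 and 0.2192 in the difference at 6 h and 24 h, and the apoptosis genes 0.1711 with the mimic at 6 h. NF-kB targets would be 0.1437 with anti-miR-21 and 0.1412 in the difference at 24 h. The integrated stress list would be 0.0854 and 0.1249 with anti-miR-21, -0.0804 with the mismatch control at 24 h, and 0.0943 and 0.1943 in the difference. Oxidative stress genes would be -0.2555 with the mismatch control and 0.2543 in the difference at 24 h. Immediate early genes would be 0.2379 and 0.2011 with anti-miR-21 and 0.2104 and 0.1648 in the difference. TGF-beta targets would be -0.1040 and histones -0.4440 with the mismatch control at 24 h, and histones 0.3802 in the difference.

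The correlation of anti-miR-21 and mimic across genes at 6 h was 0.1851, and 0.1249 with the difference from the mismatch control and 0.2338 by rank. At 24 h it was -0.0497, and 0.0148, with the sign turned, and -0.0657. Genes past the threshold in opposite directions numbered 0 at 6 h, against 2 with the difference and 6 at 1.3-fold. At 24 h they numbered 3, against 16, 35 and, with each array centred, 5. If 1 array type alone were turned, the correlation would be -0.1851 at 6 h and 0.0497 at 24 h, and 8 genes would lie in opposite directions at 24 h. The correlation of anti-miR-21 at 6 h and mimic at 24 h would be -0.301, by rank -0.351. Of the reported targets, 15 would be higher with anti-miR-21 and lower with the mimic with the Agilent arrays turned, where independent directions give 15.7, and 6 with the Affymetrix arrays turned, where they give 6.72, against 33 and 32.3. HINT3 was at 1.08 with the mimic at 6 h and at -0.0678 with the probe set of the largest absolute mean. The comparison of genes with a miR-21 seed site was not run, since no 3' UTR sequences were used here. No paired test was run, because the times are separate conditions with 1 ratio each and no test was planned.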

Other observations

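The tests named here were chosen only after the result was seen, except that of the gene families left out of the correlation. Gene families, taken as symbols with a shared start and at least 20 members, were set against random lists in the same way as the lists, and 28 of 552 such results lay outside the limits. With anti-miR-21 at 6 h, ribosomal protein genes were slightly higher: the 35 genes of the small subunit had a median of 0.10, the 42 of the large subunit 0.08, and the mitochondrial ribosomal genes 0.08 (MRPS, 28 genes) and 0.07 (MRPL, 50 genes). Zinc finger genes (ZNF, 457) had a median of -0.04 at 6 h and 0.03 at 24 h. With the mimic at 24 h, 43 of 48 MRPL genes lay above 0 with a median of 0.23, while MRPL42 was among the lowest genes, and the transcriptional repressors of the ZBTB family had a median of -0.16 over 41 genes. Nucleoporin genes (NUP) were lower with the mismatch control, at -0.07 at 6 h and -0.13 at 24 h, and small nucleolar RNAs of the SNORD class were higher at 24 h (0.12). With the mimic at 6 h, olfactory receptors had a median of 0.16 (373 genes) and keratin-associated proteins 0.18 (74 genes). The planned lists of neuronal (0.02), epithelial (0.06) and blood and endothelial genes (0.12) stayed within the range of random lists there. Their medians all lay above 0, at percentiles 70.2, 84.9 and 97.9, while housekeeping genes were at -0.11 (percentile 8.28). The values carry no expression level, so a dependence of these ratios on signal near background was not tested.

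The profile of anti-miR-21 at 6 h and that of the mimic at 24 h went together across genes, with a Pearson r of 0.30 and a rank correlation of 0.35 over 16178 genes, if both array types run in the same direction (-0.301 and -0.351 if 1 is turned), although they come from opposite treatments, different times and different array types. Gene length was argued against as the cause: both profiles were lower in longer genes, at rank correlations of -0.22 and -0.29, but within 5 classes of gene length the correlation was still at least 0.27. A few gene families were argued against too, since without ribosomal, zinc finger, olfactory receptor and keratin-associated genes it was 0.35 over 15234 genes. The higher rank correlation of the mimic at 24 h with the other treatments at 24 h was -0.0657, but a mock culture of 24 h does not enter a 6 h ratio, so that value says nothing about this pattern. What the profiles share was not found. RNA quality or growth state of single cultures may contribute, and no biological explanation was tested.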
